A study of Homo sapiens with 2 samples.

How the data were processed

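Total RNA, by its labels from A2780s ovarian cancer cells, was measured on 2 arrays, 1 labelled as CXCL14-treated and 1 as control, grouped by the treatment given in the labels. Per the labels' protocols, ribosomal RNA was removed, the remaining RNA was amplified by random priming along whole transcripts, and the product was labelled with Cy3. The arrays were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The deposited scanner files give each spot's intensity on a linear scale, background-subtracted and detrended by the scanner software and not scaled between arrays, per the file headers. The multiplicative detrending differed between the arrays: its surface had an RMS of 0.0615 on the array labelled CXCL14 and 0 on the control array, per the file headers. The authors' deposited value table holds log2 values of 58944 study probes, 1 fewer than the scanner files. Its columns had medians of 5.40 and 5.40 and correlated with the log2 scanner signals of the same arrays with r of 0.999 and 0.999, so the scale is log2 and the direction is that of the signal, while the normalization behind it is not given in the sources used here. Both arrays carried the same scan identifier and scan time and lay at different positions on the slide. Batches of RNA extraction, labelling and hybridisation are not given in the sources used here.

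Spots that the scanner software marked as outliers were left out (54 study probes on the array labelled CXCL14 and 15 on the control array), as were control spots in all counts of study probes. Values were log2 of the processed signal minus the log2 of each array's 75th percentile over the study probes. Repeated spots of a probe were averaged on the log2 scale, and different probes of GAPDH and of PGK1 were kept apart. A probe counted as detected where the scanner software called it well above background. Counts were taken over probes detected on both arrays with a log2 difference of at least 1 in size. A probe not well above background on one array has only a bound there, given as "at least N-fold", with the dim array's value set to the higher of the probe's own signal and the lowest detected signal (16.7 on the array labelled CXCL14 and 23.5 on the control array). With 1 array per group no test was run. The technical error of a named probe is the root of the summed squares of the SDs between its spots on each array. The median of that SD over the named probes was 0.0840 on the array labelled CXCL14 and 0.0279 on the control array. For probes with 1 spot, the scanner software's error of the signal was carried to the log2 difference.

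The groups, the threshold, the gene lists, the rule for named genes and the other settings to be tried were chosen before the data were examined. The rule named CXCL14, LINC00092 and the PFKFB genes, the genes with the largest changes in each direction that kept their sign and size with normexp and quantile normalization, up to 2 members at each end of every list, and the largest bounds. Where files pair probes with no gene name, it allowed 2 probe IDs in each direction, from brighter probes meeting the same conditions; 8285 higher and 4348 lower probes met them. The plan counted noncoding and coding probes apart. The files used here pair the study probes with neither a class nor a gene, so all study probes were counted together. Symbols of the 20 accessioned probes came from the RefSeq table of human assembly GRCh38.p14, in which all 20 accessions matched, and its coordinates were not used. Values are given for 18 of these genes, and the other 2 enter the counts but are not reported here by name. Using all 20 was a choice made after their values were seen, as was the use of the 12 control probes named for GAPDH and PGK1 of 3 species. The gene lists held 750 symbols in 32 lists. Only 3 lists had a named member and none had 5, the minimum set for a median, so values are given alone.

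The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes detected on both arrays, loess with a span of 0.3, the authors' values, no filter on detection, a filter on the brighter array's level, a count limited to differences beyond 2 scanner errors, the brightest human probe of a gene, and saturated probes left out. Normexp was run on the median spot intensity in place of the planned mean. Leaving the arrays unscaled was added after the data were seen. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9. The counting step was tested on a simulated pair of arrays with 58879 probes. Simulated probes counted as detected where their signal passed a fixed cutoff, in place of the scanner software's call, which was thus not tested. Changes were set only in brighter probes. Of probes changed 3-fold, 10-fold and 100-fold that were detected on both arrays, 49 of 49, 40 of 40 and 29 of 29 passed 2-fold, and 1 of 50 changed 1.5-fold did so. None of 28951 unchanged probes passed it. Nearly all detected probes of the simulated pair were unchanged. On the real arrays, 70.1% of probes detected on both passed 2-fold after the main scaling. The simulation did not test scaling where most probes differ, so it gives no rate of false calls for the counts reported here.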

Results

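RNA labelled as that of A2780s cells, an established human ovarian cancer line, was measured on a single-colour array with probes for human long noncoding RNAs and coding transcripts. 1 array carried RNA labelled as coming from cells given recombinant CXCL14, a secreted chemokine, and 1 array carried RNA labelled as coming from control cells. There were no replicates, so no difference given here has a replicate check, and no p-value is given. The errors are technical: the SD between repeated spots of one probe on one array, or the error given by the scanner software. Each array held 61184 spots, among them 58945 study probes printed once each. Of the 58879 study probes usable on both arrays, 34257 (58.2%) were well above background on the array labelled CXCL14 and 37428 (63.6%) on the control array. The same call, in most spots, also passed 14 of the 60 probes named Negative on the array labelled CXCL14 and 7 on the control array. Medians of Negative probes reached 819 and 520, so counts of detected probes can include background signal. Over the study probes, the median processed signal was 30.5 on the array labelled CXCL14 and 58.1 on the control array, and no study probe was saturated. The precision is limited by the number of arrays, 1 per group.

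The comparison asked which transcripts differ in ovarian cancer cells given CXCL14, and the study's title names LINC00092 and glycolysis. Gene names could be read for 20 probes with a human RefSeq accession, each repeated over 7 to 10 usable spots, and for 12 control probes named for GAPDH or PGK1 of human, mouse or rat. Most of these human transcripts gave less signal on the array labelled CXCL14, and several abundant ones gave almost none. ACTG1, which encodes cytoplasmic gamma-actin, had a median signal of 62.0 on the array labelled CXCL14 and 328101 on the control array, a log2 difference of -11.05 ± 0.11 (technical SD) after scaling each array to its 75th percentile. The probes named for mouse and rat GAPDH and PGK1 went the opposite way in 5 of 8 cases. Rat-GAPDH_3 gave 210583 on the array labelled CXCL14 and 89.3 on the control array, and Mouse-GAPDH_5 gave 179986 and 253. Some human-named and rodent-named probes of the same genes, given below, moved apart, which leaves the source of that array's RNA in doubt. Directions therefore refer to the array labelled CXCL14 and not to an effect of CXCL14.

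COX4I1, a subunit of cytochrome c oxidase, was at 0.0544% of its control signal before scaling, with a scaled log2 difference of -9.56 ± 0.07. EIF3D, a translation initiation factor subunit, was at 0.0804%, with a log2 difference of -9.00 ± 0.11. DYNLL1, a dynein light chain, differed by -7.98 ± 0.08 and RACK1, a scaffold protein bound to the ribosome, by -7.00 ± 0.13. MTX1, a protein of the mitochondrial outer membrane, differed by -5.95 ± 0.30. Of the 16 named genes with a control signal over 10000, 7 were under 1% of that signal on the array labelled CXCL14. ACTG1, COX4I1, EIF3D, DYNLL1, RACK1 and MTX1 were at least 2-fold lower in all 6 settings of background and scaling, which include no scaling.

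Other named genes were closer between the arrays. PRMT1, an arginine methyltransferase, differed by -1.13 ± 0.08 and ODC1, the first enzyme of polyamine synthesis, by -1.004 ± 0.08, and was at least 2-fold lower in 5 of the 6 settings. The actin-binding protein PFN1 differed by -0.73 ± 0.09, ARHGDIA by -0.62 ± 0.08 and the beta-actin gene ACTB by -0.18 ± 0.05, and all 3 were lower in each of the 6 settings. PFN1 was at least 2-fold lower in 5 settings, ARHGDIA in 4 and ACTB in 3. H3-3A, which encodes a replacement histone H3, gave 142397 and 137364, a log2 difference of 1.37 ± 0.08 after scaling that turned to -0.05 with loess and passed 2-fold in 2 settings. GRM4, a glutamate receptor, gave 105 and 72.1, a log2 difference of 1.71 ± 0.25. It was higher in all 6 settings and at least 2-fold higher in 4 of them. Both GRM4 signals lay below the highest medians of the probes named Negative, 819 and 520, so they may be background. Of the 18 named genes well above background on both arrays, 10 were at least 2-fold lower on the array labelled CXCL14, 2 were at least 2-fold higher and 6 lay within 2-fold. With loess 14 were lower and 0 higher, and with no scaling 13 were lower and 0 higher. Without scaling, 18 of all 20 named genes gave less signal on the array labelled CXCL14.

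**Figure D1:**
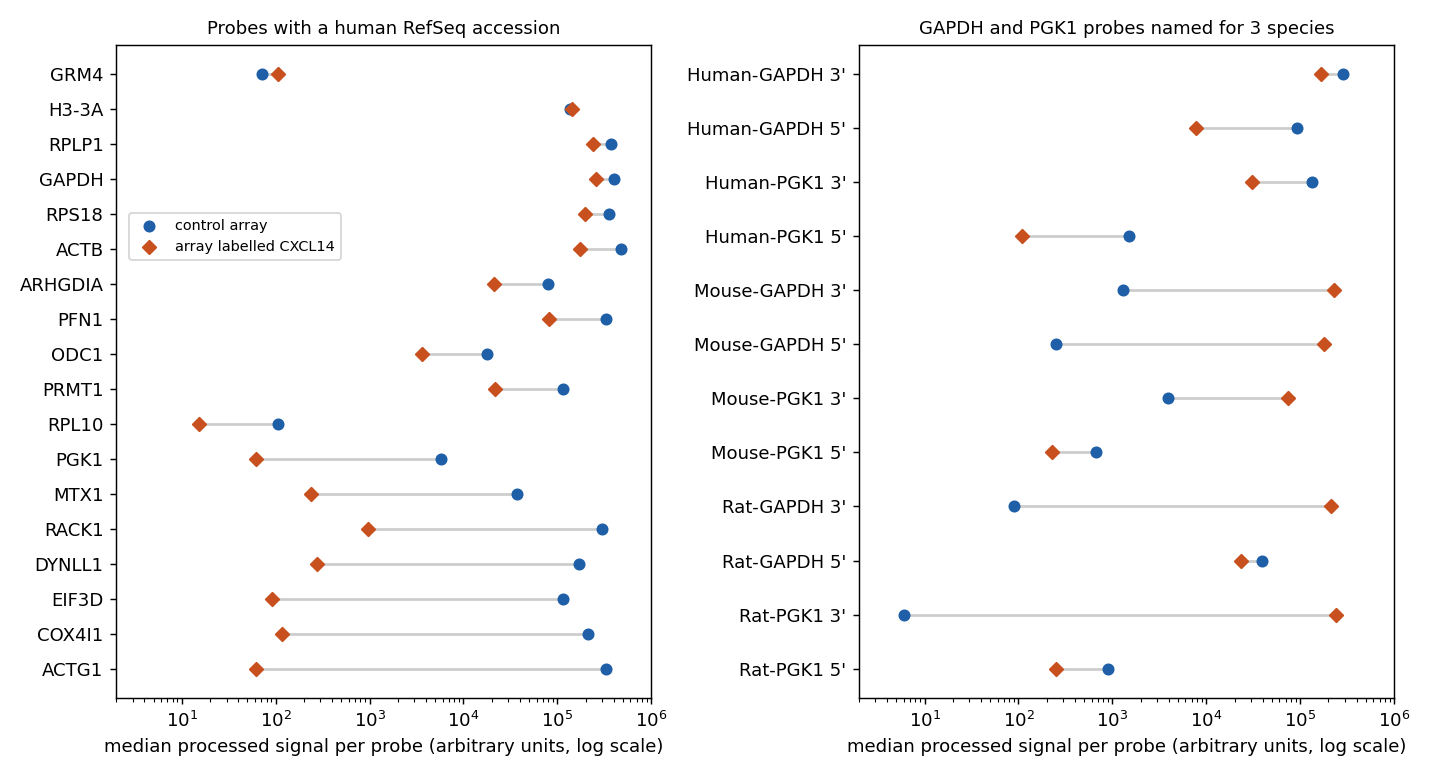
Median processed signal (arbitrary units, log axis) of each gene-named probe on the control array (circles) and on the array labelled CXCL14 (diamonds), before scaling between arrays, with 18 of the 20 human-accessioned probes on the left and the 12 GAPDH and PGK1 probes named for 3 species on the right. ACTG1 lies at 62.0 on the array labelled CXCL14 against 328101 on control, while Rat-GAPDH_3 lies at 210583 against 89.3.

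Glycolysis was represented by GAPDH and PGK1, both enzymes of its lower part, and these probes did not move together. The accessioned GAPDH probe gave 254939 on the array labelled CXCL14 and 399847 on the control array, a log2 difference of 0.67 ± 0.10 after scaling, and over the 6 settings it was higher in 3 and lower in 3, down to -0.91 with loess. The accessioned PGK1 probe gave 61.7 and 5702, a log2 difference of -5.23 ± 0.10, and was lower in all 6 settings. Human-PGK1_3, by its name a probe near the 3′ end of the transcript, gave 30545 and 133492, a scaled log2 difference of -0.81 that lay within 2-fold, and Human-PGK1_5, near the 5′ end, gave 109 and 1497. Human-PGK1_3 was lower in all 5 settings tried for the control probes, no scaling included, and at least 2-fold lower in 4. Human-GAPDH_3 gave 167926 and 287986, and over the same 5 settings it was higher in 2 and lower in 3. Human-GAPDH_5 gave 7756 and 92164 and was lower in all 5.

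Probes for the same genes of mouse and rat were bright on the array labelled CXCL14. Mouse-GAPDH_3 gave 227329 on that array and 1311 on the control array, a scaled log2 difference of 8.73. Mouse-PGK1_3 gave 73831 and 3927, a difference of 5.49, and Mouse-GAPDH_5 differed by 10.75. Rat-GAPDH_3 differed by 12.51. Rat-PGK1_3 gave 243228 and was not well above background on the control array, which makes it at least 25280-fold higher after scaling and at least 10382-fold higher before it. These 5 probes were higher in all 5 settings. The other 3 rodent-named probes gave less signal on the array labelled CXCL14 before scaling: Mouse-PGK1_5 gave 230 against 664, Rat-PGK1_5 gave 251 against 892, and Rat-GAPDH_5 gave 23580 against 38795. Over the 5 settings, no scaling included, Rat-GAPDH_5 was higher in 3 and lower in 2, and both PGK1_5 probes were lower in all 5.

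Ribosomal proteins were represented by RPLP1 and RPS18 from the list fixed in advance, and by RPL10. RPLP1 gave 239237 on the array labelled CXCL14 and 371770 on the control array, a scaled log2 difference of 0.68 ± 0.10, and was higher in 3 of the 6 settings and lower in 3. RPS18 gave 194846 and 350506, a difference of 0.46 ± 0.08, and was higher in 2 settings and lower in 4. RPL10 was well above background in 1 of its 10 spots on the array labelled CXCL14 and in all 10 on the control array, where its median was 107, which makes it at least 2.64-fold lower. With normexp the log2 difference of RPL10 was -0.15, and it was at least 2-fold lower in the other 5 settings. Its control signal lay below the highest median of a probe named Negative there, 520, so it may be background. Oxidative phosphorylation was represented by COX4I1 alone. No other list fixed in advance had a member among the named probes, so 29 of the 32 lists have no value. The files used here do not pair the study probes with gene names, and CXCL14, LINC00092 and the PFKFB genes, which encode regulators of glycolysis, have no value here.

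Across the study probes, 29118 (49.5%) were well above background on both arrays. Of these, 14871 (51.1%) were at least 2-fold higher on the array labelled CXCL14 after scaling, 5540 (19.03%) were at least 2-fold lower and 8707 (29.9%) lay within 2-fold. A further 5139 study probes were well above background only on the array labelled CXCL14, of which 843 were at least 10-fold higher, and 8310 only on the control array, of which 2450 were at least 10-fold lower. ASHGA5P010760 gave 174133 against 30.4, a log2 difference of 13.77 with a scanner error of 0.30, and ASHGA5P006207 gave 150161 against 176, a difference of 11.02 with an error of 0.21. In the other direction, ASHGA5P044525 gave 44.3 against 326570, a difference of -11.57 with an error of 0.24, and ASHGA5P003947 gave 30.2 against 198467, a difference of -11.40 with an error of 0.27. The log2 difference had a median of 1.04 and an SD of 2.20 over probes, against a median scanner error of 0.215. After this scaling, 25229 probes (86.6%) differed by more than 2 scanner errors. That share includes the median shift of 1.04 and was not computed under the other scalings. The scanner error leaves out the spread between arrays. The balance of directions followed the scaling: 72.9% of the probes past 2-fold were higher after 75th percentile scaling, 57.0% after scaling to the median of detected probes, 44.2% after loess and 29.7% with no scaling. The 75th percentile scaling moved the array labelled CXCL14 up by 1.28 on the log2 scale relative to control.

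**Figure D2:**
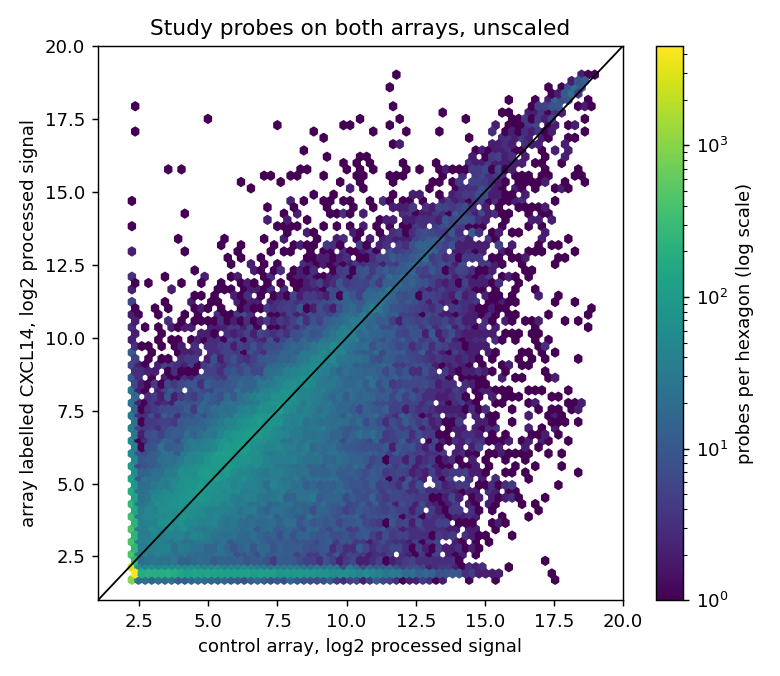
Log2 processed signal of study probes on the control array (horizontal axis) and on the array labelled CXCL14 (vertical axis), before scaling, as a density of probes per hexagon on a log colour scale, with a line of equal signal. Many probes bright on the control array reach down to the floor of the array labelled CXCL14, and Pearson's r over 58879 probes was 0.67.

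Log2 levels of the 29118 probes detected on both arrays correlated with a Pearson coefficient of 0.66 and a Spearman coefficient of 0.58, across probes, which are not independent replicates. The brightest study probes of the control array split widely. Of the 1000 brightest, 532 (53.2%) lay within 4-fold of their control signal on the array labelled CXCL14 before scaling, and 260 (26.0%) lay under 1% of it. In the other direction, 33 (3.3%) of the 1000 brightest study probes of the array labelled CXCL14 lay under 1% of their signal there on the control array. The 2 sets of 1000 shared 553 probes. The bright rodent-named GAPDH and PGK1 probes and the human transcripts under 1% of control, such as ACTG1 and COX4I1, were on the same array, so no count of study probes here separates the treatment from that difference.

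**Figure D3:**
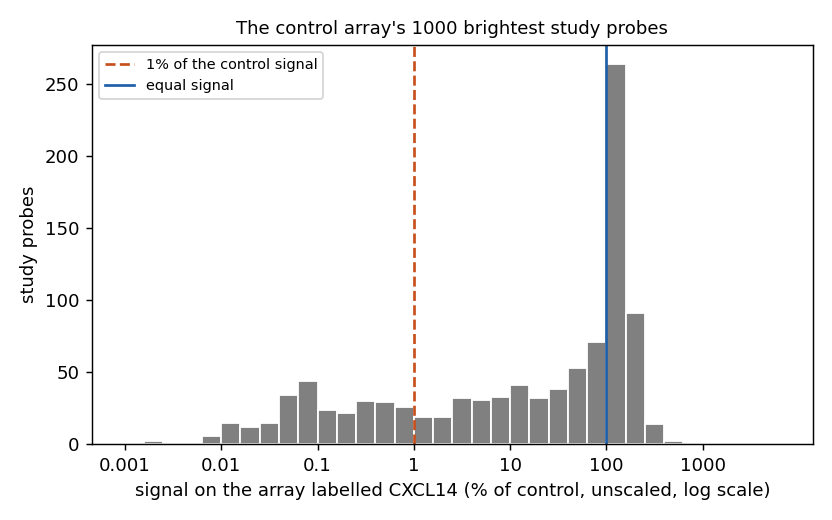
Histogram of the control array's 1000 brightest study probes by their signal on the array labelled CXCL14 as a percentage of the control signal, before scaling (log axis), with lines at 1% and at equal signal. 260 probes lie under 1% and 370 lie between 100% and 400%.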

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

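The tests on rodent-named probes, grid position, RNA degradation and a response to CXCL14 were chosen only after the result was seen. The test on the study's own bright probes and the test of labelling yield were fixed before their results were seen.

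5 control probes named for mouse or rat genes, outside the study's own probes, were far brighter on the array labelled CXCL14 than on the control array. Mouse-GAPDH_3 gave 227329 there, Mouse-GAPDH_5 gave 179986, Mouse-PGK1_3 gave 73831, Rat-GAPDH_3 gave 210583 and Rat-PGK1_3 gave 243228. On the control array they gave 1311, 253, 3927, 89.3 and 6.06. On the array labelled CXCL14 human transcripts such as ACTG1 and COX4I1 were at 0.0193% and 0.0544% of their control signal.

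A biological response of A2780s cells to CXCL14 as the whole cause was weighed on the GAPDH probes, which a change in GAPDH level would move together. They moved apart by up to 27728-fold before scaling, between Rat-GAPDH_3 and Human-GAPDH_5. At the 3′ end, Rat-GAPDH_3 was 2399-fold higher and Human-GAPDH_3 was at 0.590 times control. Rat-GAPDH_3 helped raise the question, and gave only 89.3 on control, so it may not follow human GAPDH. The gap argues only against a change in GAPDH level as the cause of both, and leaves other responses open. Low labelling yield is argued against as the whole cause by the probes detected on both arrays. Of these, 1.82% were over 10 times brighter on the array labelled CXCL14 before scaling. A lower yield beside another cause stays open, as 11.5% were 10 times dimmer or more there. Misplaced spots are argued against by a correlation of 0.68 at no shift, against at most 0.0153 at shifts of up to 4 rows and 4 columns each way. Degraded RNA lowers signal, whereas 4 of the 6 probes for the 3′ end of GAPDH or PGK1 were 10 times brighter or more before scaling. These 4 are rodent-named probes that raised the question, and both human-named ones gave less signal. They argue against degradation only as the cause of the brightening. A part played by degradation stays open. The 5′ to 3′ signal ratio of the human-named pairs was 0.147 times that on control for GAPDH and 0.319 times for PGK1. Of all 6 pairs, 5 had a lower ratio than on control and 1, mouse GAPDH, a higher one (4.06 times). These ratios also depend on how well the RNA matches each probe, so they cannot decide it. A candidate explanation that remains is RNA of a mouse or rat sample on the array labelled CXCL14. It was prompted, not tested, by the 5 of 8 rodent-named probes that were 10 times brighter or more. Its prediction required at least 20% of the control array's 1000 brightest study probes under 1% of their control signal, and 26.0% were. That share cannot tell rodent RNA from any other loss of human transcripts. Such a loss was also seen in the named genes, where 7 of 16 bright on control were under 1%. Both species' probes were bright, so which rodent it may be stays open, as does the step at which such RNA could have entered.

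Of 56 other control probes outside the comparison, 5 were well above background on the array labelled CXCL14 and in no spot on the control array, with no overlap of their spots, and 2 the other way round. ETG10_13482 gave 151 against 4.697 and ERCC-00075_180 gave 49.96 against 4.697. (+)E1A_r60_a107 gave 28.7 against 10.1, DCP_22_4 gave 27.3 against 17.7 and DCP_22_7 gave 27.7 against 21.3. In the other direction, ERCC-00043_129 gave 4.96 against 91.7 and DCP_1_4 gave 9.65 against 42.3. Among the 60 probes named Negative, 10 were well above background in most spots on the array labelled CXCL14 and also had every spot there brighter than every spot on the control array.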

How the results depend on the processing

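Leaving the arrays unscaled was chosen after seeing the data; the other alternatives were planned. Against 14871 study probes at least 2-fold higher and 5540 lower, the count of higher probes was 9427 with scaling to the median of detected probes, 6531 with loess and 4172 unscaled, and that of lower probes was 9894 unscaled. These shifts follow from the scaling, which moves all differences of an array pair together, or, for loess, those at each level. With no filter on detection the counts were 28081 and 12815 over 58879 probes, and with the brighter array above the median level 9855 higher over 18976 probes, as more or fewer probes were counted. Normexp gave 12308 and 4620, quantile normalization 13712 and 5718, and the authors' values 13668 and 5727, within 1.5 times the main counts. Requiring 2 scanner errors removed 1 probe, and no probe was saturated, so leaving such probes out tests nothing. H3-3A turned from 1.37 to -0.0513 with loess; the cause was not tested. Of 174 alternatives over the 36 named probes, this 1 reversed a difference past 2-fold, 8 moved a value by less than the scanner software's error of it and 165 by more. The brightest human probe left GAPDH at 0.67 and put PGK1 at -0.81 in place of -5.23. Percentiles of random lists (no list had 5 members) and the authors' values and detection filters for named control probes were not run. No paired analysis was possible because each group has 1 array. Signal over background limits the dim end: 16312 probes were detected on neither array.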

Other observations

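The test of a CXCL14 response in addition to the source of the bright rodent-named probes was chosen only after the result was seen. The test of a share of human RNA was fixed before its result, but after the loss of signal in the named genes was known.

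Named genes spread widely in the share of control signal they gave on the array labelled CXCL14, and those listed here were chosen after their values were seen. Before scaling, the RPLP1, GAPDH, RPS18 and ACTB probes gave 65.8%, 65.2%, 56.6% and 36.2% of their control signal (the first 3 were higher than control in some scaled settings). PFN1, ODC1 and PRMT1 gave 24.7%, 20.5% and 18.7%, and RACK1, DYNLL1 and ACTG1 gave 0.321%, 0.163% and 0.0193%. ACTB and ACTG1, the genes of the cytoplasmic actins, whose proteins are nearly identical, thus lay far apart. The study's own probes were spread over a similar range: of the control array's 1000 brightest, 129 lay under 0.1% of their control signal, 131 between 0.1% and 1%, 134 between 1% and 10%, 73 between 10% and 25%, 65 between 25% and 50%, 97 between 50% and 100%, and 370 between 100% and 400%.

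Human RNA making up 10% or more of the labelled RNA would be expected to leave about that share of each control signal, and so few probes under 1%. Of the control array's 1000 brightest study probes, 260 lay under 1%, which argues against such a share. This is the count behind the 26.0% given for rodent RNA above, so it is not a separate result. Whether CXCL14 changed any transcript in addition cannot be told apart from whatever made the rodent-named probes bright, because 0 arrays labelled CXCL14 lacked the bright rodent-named probes.

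Some other control probes were close between the arrays. ERCC-00062_278, the brightest of the ERCC-named probes on both arrays, gave 1114 on the array labelled CXCL14 and 1227 on the control array, and the GE_BrightCorner spots gave 24331 and 22223.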
